A study of Urocitellus parryii with 3 samples.

How the data were processed

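The deposited data are 3 Illumina libraries of small RNA from arctic ground squirrel liver. Per the labels' protocols, total RNA of the animals of a stage was mixed in equal amounts, about 10 µg per stage was separated on a gel, RNA of 18 to 30 nt was cut out, adapters were ligated and the product was amplified by 15 cycles of PCR. Hibernating animals were kept through at least 4 torpor bouts and sampled on day 4 of a bout, per the labels, which do not say how that day applies to the animals in early arousal. Libraries made from mixed RNA average the animals of a stage and hide their spread.

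The authors deposited 1 table of genome positions. Per the file headers, each entry joins a read sequence, its read count and the stage, so the unit is a whole-number read count held inside a text entry and not a numeric column. The counts were used as deposited and are not scaled to depth. All reads are 30 bases long. The leading part that was placed on a genome scaffold is in capitals, at least 18 bases, and the rest is in lower case. The aligner, the genome build and its species, the read filters and any miRNA annotation are not given in the sources used here. The table has 866747 lines with a position on 61932 named scaffolds, and positions start at 1. A sequence placed at several positions carries the same count at each, without exception in 4218154 entries, so each sequence was counted once per stage. The table holds placed reads only. A miRNA whose locus is missing from, or differs in, the genome used leaves no reads, and its reads with sequencing errors can be placed elsewhere.

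The 3′ adapter was searched in each read with up to 1 mismatch in 5 bases, for inserts of 18 to 26 nt. Reads were matched to 159 mature miRNA sequences, mostly human and rodent forms, written down from general knowledge before the data were examined and not checked against a miRNA database. A read had to start at the same base, share the first 18 bases and differ from the listed sequence only in length or in its last 3 bases. Reads matched equally well by several miRNAs were split equally, which concerned 0.195% of miRNA reads. Near-identical family members such as the let-7 miRNAs, or miR-103-3p and miR-107-3p, can still exchange reads through sequencing errors. No reference genome was used here, so sequences matched to no listed miRNA are given by sequence alone. An item among these sequences is not reported here.

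Counts were scaled by trimmed mean of M-values factors over the miRNA counts (30% trimmed on ratio and 5% on abundance), computed by own code in Python 3.11.15 with numpy 2.4.6. A package implementation was planned, but the counts sit inside text entries, so the same formula was coded directly. The factors were 0.984 for post-reproduction, 1.07 for early arousal and 0.950 for late torpor. Values are normalised counts scaled to CPM. A miRNA with no read in a library lies under the limit that 3 counts allow, which was 0.584, 0.549 and 0.570 CPM in post-reproduction, early arousal and late torpor. PCR reads carry no molecular identifiers, so intervals and limits cover counting error only.

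Samples were grouped by the stage in the labels. Because each stage has 1 library, no test across replicates was made and no p-value is given. Ratios have exact conditional binomial (Clopper-Pearson) 95% intervals and shares have exact binomial ones, from scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. The count reported for each comparison is the number of miRNAs at least 2-fold different among those with at least 100 reads over both libraries. The miRNAs named were fixed by rule: the 10 largest and 10 smallest ratios that passed 2-fold with an interval excluding 1, the 10 most abundant of each library, up to 4 abundant members of each list, and miR-122-5p, miR-451a-5p and miR-210-3p. Others named were chosen after their values were seen, such as miRNAs without reads, apart from those listed at the 1.5-fold limit, a limit fixed before the data were examined.

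Lists of miRNAs (18) were fixed before the data were examined. They cover hepatocyte-enriched, erythroid, leukocyte, mesenchymal and stellate, endothelial, biliary and other epithelial, muscle, neural, pancreatic, lipid and glucose metabolism and hypoxia-induced miRNAs, the let-7, miR-29, miR-30 and miR-15/16 families, the miR-17-92 and paralogous clusters, the miR-23/27/24 clusters and the pair of miR-221-3p and miR-222-3p. A member counted as detected with at least 10 reads in all and at least 1 in each library, which 108 miRNAs had. The median log2 ratio of a list is given with its percentile among 10000 random lists of the same size matched on mean abundance, as a description of these libraries. The 3′ ends were tabulated for 41 miRNAs with at least 1000 inserts in each library.

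The code was tested on simulated data. For late torpor against post-reproduction with 122 miRNAs, 119 of 120 simulated 3-fold differences and 1 of 120 simulated 1.5-fold differences were called at 2-fold. Of unchanged miRNAs, 0 of 1348 were called, and the interval held 1 in 1267 of 1328 (95.4%). The second count left out the miRNA with most of the reads, so the coverage of its narrow interval was not tested. Nor does the simulation test the intervals against differences between real libraries. Of simulated reads, 98.5% were assigned to their miRNA and 99.1% had their insert length found. The first of these rates does not measure how many real miRNA reads the matching rule loses. Real reads with a shifted start or an error in the shared first bases are not assigned to their miRNA under that rule. Alternatives changed the scaling, the minimum count, the fold limit, the matching of reads, the treatment of tied and multiply placed reads and the grouping by seed.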

Results

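Small RNA was sequenced from the liver of the arctic ground squirrel (Urocitellus parryii), a rodent that spends the winter in bouts of torpor broken by short arousals. Animals in late torpor and in early arousal came from the hibernation season, and post-reproduction animals in summer served as the non-hibernating reference. Per the labels, the light cycle was 16 h light and 8 h dark for post-reproduction. It was 4 h light and 20 h dark for late torpor and early arousal, so hibernation and light cycle cannot be told apart in comparisons with post-reproduction. RNA of 6 post-reproduction, 4 early arousal and 4 late torpor animals was mixed within each stage, so each stage is 1 library and the 14 animals give no replicate. No test between stages was possible. All intervals given here are 95% intervals that cover counting error only, and every ratio compares 2 libraries, not 2 stages. The table held 5614441 placed reads from post-reproduction, 5611673 from early arousal and 5860476 from late torpor.

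Liver miRNA in all 3 libraries was dominated by miR-122-5p, the abundant hepatocyte miRNA, and by the let-7 family. Reads assigned to listed miRNAs made up 93.0% of the placed reads in post-reproduction, 90.9% in early arousal and 94.6% in late torpor. Within these reads miR-122-5p took 80.3% in post-reproduction (exact interval 80.2 to 80.3), 78.6% in early arousal (78.5 to 78.6) and 80.5% in late torpor (80.4 to 80.5). The second miRNA, let-7f-5p, took 10.5%, 11.7% and 11.2% in the same order. let-7a-5p followed at 19835, 21349 and 21581 normalised CPM (counts scaled by library size), and let-7c-5p at 12900, 11383 and 11359. Among the other abundant miRNAs, miR-29a-3p stood at 5030, 5210 and 5224 CPM and miR-378a-3p, which is encoded within a gene of mitochondrial energy metabolism, at 4481, 2915 and 3131. Of 159 listed mature miRNAs, 122 had at least 1 read. The other 37 had no placed read, among them miR-192-5p, miR-194-5p and miR-148a-3p, which are usually abundant in liver, and the hypoxia-induced miR-210-3p. Because the table lists only reads placed on genome scaffolds, of a species and build not stated, a missing miRNA was not shown to be absent from the tissue. The miR-122-5p reads were placed on the plus strand of GeneScaffold 256, from 347042 to 347064, in a genome build not given in the sources used here. No gene annotation of these scaffolds was used here.

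The comparison of late torpor with post-reproduction asked how liver miRNA differed between deep hibernation and the summer state. Red-cell miRNAs were higher in the late torpor library. miR-451a-5p, a miRNA of the erythroid lineage, was 2.11-fold higher (interval 1.85 to 2.41; 717 against 331 reads) and was the only miRNA with at least 100 reads over both libraries to be at least 2-fold higher. Its cluster partner miR-144-3p had a ratio of 1.81 (1.43 to 2.30) and miR-486-5p, also abundant in red cells, one of 1.28 (1.14 to 1.44). With 1 internal mismatch accepted, miR-144-3p also passed 2-fold, at a log2 ratio of 1.004. On the lower side, miR-10a-5p, which lies in a HOX gene cluster, had a ratio of 0.476 (0.413 to 0.548) and the epithelial miR-200a-3p one of 0.479 (0.363 to 0.628). Both were more than 2-fold lower, but under median-of-ratios scaling miR-200a-3p fell just short of it, at a log2 ratio of -0.996. With 1 internal mismatch accepted both fell short, each at -0.96, and with shifted starts accepted miR-10a-5p did, at -0.99. miR-122-5p itself differed little, with a ratio of 1.04 (1.04 to 1.04).

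Of 86 miRNAs with at least 100 reads over these 2 libraries, 78 lay within 1.5-fold of each other. The interval lay above 1 for 19 miRNAs, below 1 for 33 and held 1 for 34, and the log2 ratios had a median of -0.06 and an SD of 0.38 across miRNAs. At a 1.5-fold limit, 3 miRNAs were higher and 5 were lower in late torpor. Those not yet named were the leukocyte miR-142-5p at 1.72 (1.48 to 2.02), miR-184-3p at 0.573 (0.545 to 0.602), miR-152-3p at 0.560 (0.535 to 0.587) and miR-320a-3p at 0.585 (0.561 to 0.610). miR-320a-3p is named because of its value and not by the naming rule. For miR-142-5p, 84.4% of the post-reproduction reads and 81.4% of the late torpor reads began at another base than the listed one and are not in that ratio. With them it was 1.47 (1.38 to 1.57), short of the 1.5-fold limit. With reads identical to the listed sequence only, 36 in all, the log2 ratio of miR-200a-3p was -0.39 (-1.45 to 0.63) in place of -1.06. That of miR-320a-3p was then -0.47 (-0.57 to -0.37), short of 1.5-fold.

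As a group, the 3 erythroid miRNAs had a median ratio of 1.81, at percentile 99.6 of random lists matched on abundance, with all 3 intervals above 1. The miR-17-92 and paralogous clusters, growth-associated miRNAs, had a median of 1.3 at percentile 98.9 over 7 of 11 members detected, with 3 intervals above 1. Those were of 3 miRNAs that lie together on GeneScaffold 4329. There miR-93-5p had a ratio of 1.48 (1.3 to 1.68), miR-106b-5p 1.43 (1.16 to 1.78) and miR-25-3p 1.3 (1.17 to 1.43). The intervals of miR-17-5p at 1.28 (0.984 to 1.68), miR-20a-5p at 0.933 and miR-92a-3p at 0.947 held 1, the last 2 named after their values were seen. The mesenchymal and stellate list had a median of 0.815 at percentile 3.44, with 6 of 9 intervals below 1 and none above. Its most abundant members were miR-199a-3p at 0.815 (0.794 to 0.837) and miR-143-3p at 0.785 (0.763 to 0.809). The epithelial list had a median of 0.760 at percentile 12.3. The pair of miR-221-3p and miR-222-3p had 0.778 at percentile 22.4, the neural list 0.849 at percentile 15.4 and the lipid and glucose list 0.861 at percentile 15.0. Of the rest, the let-7 family had a median of 0.955, the leukocyte list 0.897, the miR-29 family 0.923, the miR-30 family 0.863, the miR-15/16 family 0.983 and the miR-23/27/24 clusters 0.991. With identical reads only, the leukocyte list, then of 2 members, had a log2 median of 0.81 in place of -0.16. The endothelial pair had 1.26 at percentile 92.6, with neither interval excluding 1, the muscle list 1.11 at percentile 84.5 and the hepatocyte list 1.02, the last with 3 of 8 members detected. No member of the pancreatic or hypoxia lists was detected in all 3 libraries. Over the 3 comparisons, 4 of 48 list medians lay outside the central 95% of random lists, where independent members would give 2.4. Members that lie together, such as miR-451a-5p and miR-144-3p, need not vary independently, so chance can give more. The 4 were the erythroid list in each comparison and the miR-17-92 and paralogous clusters in this one.

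The comparison of early arousal with post-reproduction asked how the liver differed from the summer state as animals rewarmed. Here the red-cell miRNAs did not move together. miR-486-5p had a ratio of 0.479 (0.410 to 0.559) and miR-144-3p one of 0.569 (0.413 to 0.780), while miR-451a-5p had one of 1.2 (1.04 to 1.39). miR-184-3p, with 1441 reads against 4182, was the lowest at 0.324 (0.305 to 0.344). miR-200a-3p at 0.383 (0.285 to 0.511) and miR-152-3p, a member of the miR-148/152 family, at 0.491 (0.469 to 0.515) were also at least 2-fold lower. For miR-152-3p the log2 ratio was short of 2-fold under median-of-ratios scaling (-0.98), plain scaling (-0.90) and scaling to all placed reads (-0.94), as was that of miR-486-5p under the last 2 of these (-0.94 and -0.97). With identical reads only, both were short of it too, at -0.96 for miR-152-3p and -0.62 for miR-486-5p, and without multiply placed reads miR-486-5p had none left. The only miRNA of the 85 with at least 100 reads to be at least 2-fold higher was miR-181c-5p at 2.12 (1.51 to 2.99), from 117 against 52 reads. With identical reads only, miR-181c-5p had 19 reads and missed the minimum, while miR-1-3p (log2 1.01) and miR-181b-5p (1.24) were past 2-fold higher and miR-378a-3p (-1.17) past 2-fold lower.

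The abundant relatives of miR-181c-5p were higher in early arousal too. miR-181a-5p had a ratio of 1.56 (1.49 to 1.62) and miR-181b-5p one of 1.51 (1.41 to 1.61). Both are named because of their values, as are miR-151-3p at 1.73 (1.49 to 2.01), miR-140-3p at 0.660 (0.634 to 0.686) and miR-744-5p at 0.618 (0.525 to 0.726). For miR-140-3p, 69.9% of the post-reproduction reads and 77.4% of the early arousal reads began at another base and are not in that ratio. With them it was 0.876 (0.859 to 0.894). The muscle miRNA miR-1-3p had a ratio of 1.80 (1.76 to 1.85), and its levels were 1703, 3067 and 2366 CPM in post-reproduction, early arousal and late torpor. miR-378a-3p had a ratio of 0.650 (0.637 to 0.664), miR-10a-5p 0.523 (0.456 to 0.599) and miR-146a-5p, induced in inflammation, 0.579 (0.430 to 0.776). For miR-146a-5p the log2 ratio changed from -0.79 to 0.39 when only reads identical to the listed sequence were counted, and that of miR-151-3p from 0.79 to 0.42, each from under 100 reads. Without multiply placed reads, miR-1-3p, miR-378a-3p and miR-146a-5p had none left. Among 85 miRNAs compared, 70 lay within 1.5-fold, 5 were higher and 10 lower at that limit. The interval lay above 1 for 32, below 1 for 32 and held 1 for 21. miR-122-5p had a ratio of 0.900 (0.899 to 0.901), a log2 ratio of -0.15. That interval, like the counts of intervals above and below 1, takes the scaling as exact. Plain scaling to miRNA reads shifted every log2 ratio of this comparison by 0.12. As a share of miRNA reads, miR-122-5p held 78.6% in early arousal and 80.3% in post-reproduction.

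The erythroid list had a median ratio of 0.569 at percentile 1.92, with 2 intervals below 1 and 1 above. It was the only list outside the central 95% of random lists in this comparison. The mesenchymal and stellate list had a median of 1.18 at percentile 95.6, with 4 intervals above 1 and 3 below. The leukocyte list had 0.579 at percentile 6.60 over 3 of 8 members, with 1 interval above 1 and 1 below. That median is the ratio of miR-146a-5p, and with identical reads only the list, then of 2 members, had a log2 median of 0.19 in place of -0.79. In the muscle list, of which 2 members were detected, the median was 1.34 at percentile 91.7, and miR-206-3p had a ratio of 1.0 (0.694 to 1.45). Neural miRNAs were split, with miR-9-5p at 1.36 (1.27 to 1.46) and miR-124-3p at 0.708 (0.663 to 0.756). The let-7 family had a median of 0.955. Within it let-7b-5p stood at 0.722 (0.711 to 0.733) and let-7a-5p at 1.08 (1.07 to 1.09). The other 11 list medians lay between 0.710 for the epithelial list and 1.11 for the miR-17-92 and paralogous clusters.

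**Figure D1:**
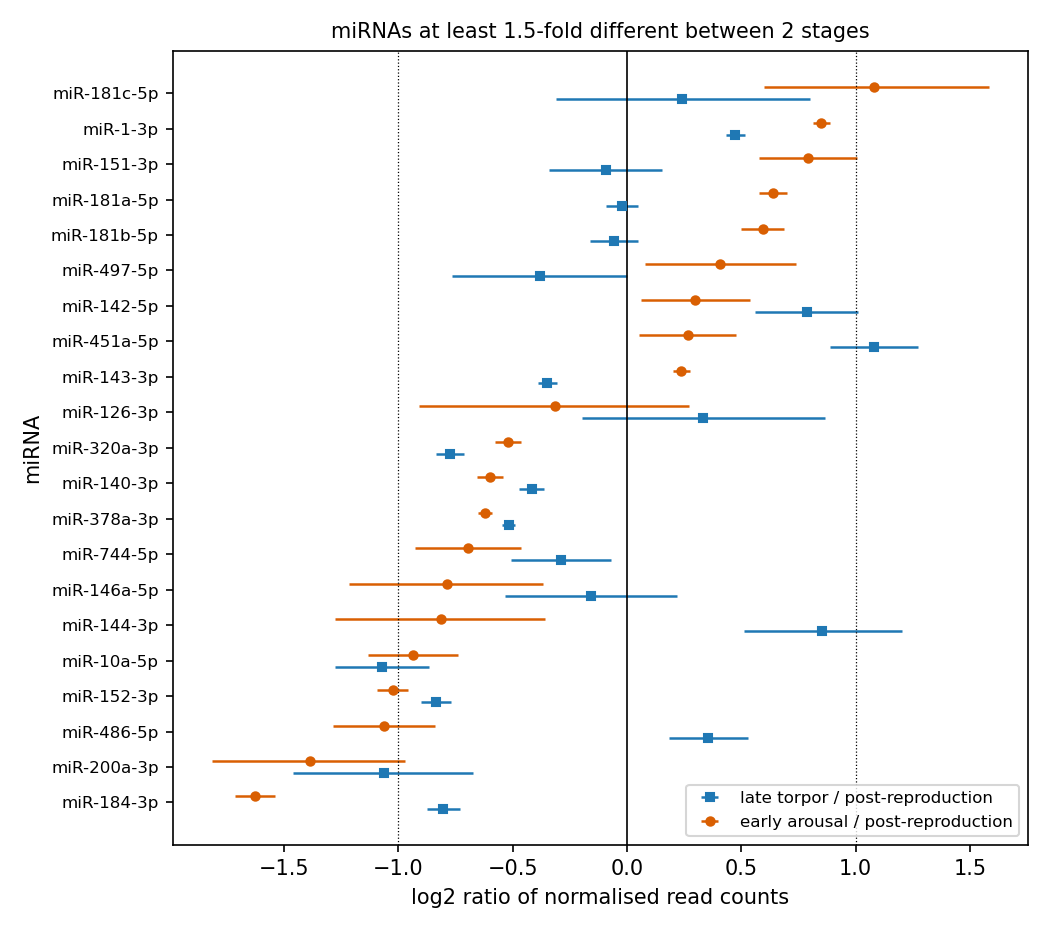
Log2 ratio of normalised read counts (x axis) for each miRNA (y axis) at least 1.5-fold different between any 2 of the 3 libraries, for late torpor (squares) and early arousal (circles) over post-reproduction, with 95% counting intervals as bars and dotted lines at 2-fold. miR-144-3p and miR-486-5p lie above 0 in late torpor and below 0 in early arousal, while miR-184-3p, miR-152-3p, miR-10a-5p and miR-200a-3p lie below 0 in both.

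Both hibernation-season libraries were set against the same post-reproduction library, so their ratios share its counting error and anything else particular to it. At the 1.5-fold limit, 4 of 85 miRNAs were lower in both: miR-10a-5p, miR-152-3p, miR-184-3p and miR-200a-3p. Simulated libraries that differed by counting error only gave 0.02 such miRNAs on average over 100 simulations, and independent lists of these sizes give 0.588. No miRNA was higher in both, where these values were 0.03 and 0.176. Neither kind of value allows for a post-reproduction library that is unusual for other reasons. Part or all of the excess may come from the shared library, since with 1 library it cannot be split. At the 2-fold limit only miR-200a-3p was lower in both, and under median-of-ratios scaling or with 1 internal mismatch accepted none was. With identical reads only, 3 were lower in both at the 1.5-fold limit, among them miR-152-3p and miR-184-3p, and 4 were higher in both. miR-10a-5p was then still lower, at log2 ratios of -1.14 in late torpor and -1.34 in early arousal, but with 94 and 91 reads missed the minimum. miR-200a-3p, at -0.39 and -1.16 from 36 and 30 reads, missed it as well.

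The comparison of early arousal with late torpor covered the change within the hibernation season and did not use the post-reproduction library. All 3 red-cell miRNAs were lower in early arousal. The ratio was 0.315 (0.235 to 0.418) for miR-144-3p, 0.374 (0.322 to 0.433) for miR-486-5p and 0.569 (0.503 to 0.642) for miR-451a-5p. The first and second of these were the only miRNAs beyond 2-fold among 86 compared. Without multiply placed reads miR-486-5p had none left, and with identical reads only miR-144-3p had 15 and missed the minimum. The erythroid list median of 0.374 lay at percentile 0.31. None of the 86 was at least 2-fold higher in early arousal. Below the minimum of 100 reads, miR-145-5p, named because of its value, had a ratio of 4.70 (2.17 to 11.6) from 39 against 8 reads.

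At the 1.5-fold limit, 6 miRNAs were higher in early arousal and 6 lower. The higher ones were miR-151-3p at 1.85 (1.59 to 2.15), miR-181c-5p at 1.79 (1.31 to 2.47), miR-497-5p at 1.72 (1.35 to 2.21), miR-181a-5p at 1.58 (1.51 to 1.65), miR-181b-5p at 1.57 (1.47 to 1.68) and miR-143-3p, expressed in smooth muscle and fibroblasts, at 1.5 (1.46 to 1.54). Besides the red-cell miRNAs, the lower ones were miR-184-3p at 0.566 (0.530 to 0.604), miR-146a-5p at 0.646 (0.477 to 0.869) and the endothelial miR-126-3p at 0.638 (0.432 to 0.936). The interval lay above 1 for 26 miRNAs, below 1 for 25 and held 1 for 35. The mesenchymal and stellate list had a median of 1.26 at percentile 97.3, with 5 of 9 intervals above 1 and none below. The leukocyte list had 0.646 at percentile 3.65 and the miR-17-92 and paralogous clusters 0.855 at percentile 9.26. The hepatocyte list had 1.40 at percentile 96.1 over only 3 of 8 members, which went both ways. Of these miR-122-5p had 0.867 (0.866 to 0.868), miR-122-3p 1.40 (1.03 to 1.89) and miR-455-3p an interval that held 1, from 11 against 5 reads. The other list medians lay between 0.784 for the endothelial pair and 1.21 for the muscle list. Plain scaling to miRNA reads, without the composition factor, shifted every log2 ratio of this comparison by 0.17, and miR-151-3p and miR-181c-5p then passed 2-fold. The log2 ratio of miR-122-5p before that shift was -0.21, and its share of miRNA reads was 78.6% in early arousal and 80.5% in late torpor. With identical reads only, the log2 ratios of miR-181a-5p (0.46), miR-451a-5p (-0.46), miR-151-3p (0.41, from 80 reads) and miR-146a-5p (-0.29) were short of 1.5-fold. Without multiply placed reads that of miR-143-3p was, at 0.57, and miR-146a-5p had none left.

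Insert lengths could be read for 85.1% of the reads in post-reproduction, 84.9% in early arousal and 88.9% in late torpor, where the adapter was found. The main length was 22 nt in each library. It held 50.5% of these reads in post-reproduction (50.4 to 50.5), 41.4% in early arousal (41.3 to 41.4) and 43.9% in late torpor (43.8 to 43.9). Inserts of 23 nt were more frequent in the hibernation-season libraries, at 32.7% in early arousal (32.7 to 32.8) and 33.0% in late torpor (33.0 to 33.1), against 25.3% in post-reproduction (25.3 to 25.4). Inserts of 21 nt held 18.3%, 18.6% and 16.9% in post-reproduction, early arousal and late torpor.

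Among inserts that the main matching rule assigned to no listed miRNA, 23 nt held 17.4% in post-reproduction, 23.7% in early arousal and 21.4% in late torpor. These inserts still include miRNA reads with a shifted start or an internal mismatch, so a difference outside miRNA is not shown.

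Most of the difference in 23 nt inserts over all reads lay in miR-122-5p, the miRNA with most of the reads. It supplied 3577031 of the 4775916 inserts in post-reproduction, 3418679 of 4766327 in early arousal and 3972163 of 5209260 in late torpor. Inserts of 23 nt were 27.3%, 36.8% and 36.7% of those of miR-122-5p in the same order. Of its inserts, 13.7% in post-reproduction were 1 base longer than the listed 22 nt and ended in U, against 23.8% in early arousal and 23.3% in late torpor. The share at the listed length was 48.6%, 36.3% and 39.7% in the same order. That U matches the next base of the genome at the locus, since the placed part of these reads extends over it. A U added to the 22 nt form would be placed over it as well, so encoded and added U cannot be told apart here. Inserts of miR-122-5p that ended in A bases beyond the placed part, and so not encoded at the locus, made up 14.7% in post-reproduction, 14.3% in early arousal and 14.6% in late torpor. Tailing with A reached 34.0%, 33.8% and 35.0% for miR-378a-3p and stood at 2.83%, 2.69% and 2.62% for miR-29a-3p. miR-101-3p had 13.8% in post-reproduction and 18.0% in each of the other libraries. Most other miRNAs also had more A tailing in each hibernation-season library, such as miR-143-3p at 7.76%, 11.4% and 11.9% in post-reproduction, early arousal and late torpor. Others had less, such as miR-184-3p at 18.3%, 15.9% and 14.9%. Inserts that ended in U bases beyond the placed part were likewise more frequent in the hibernation-season libraries for most miRNAs. For miR-122-5p they made up 2.18% in post-reproduction, 3.95% in early arousal and 2.99% in late torpor. let-7c-5p, with the largest ratios to post-reproduction, had 2.03%, 4.31% and 4.48%. Over 39 miRNAs other than miR-122-5p the median ratio of this share to post-reproduction was 1.12 in early arousal and 1.17 in late torpor, with 31 and 26 of them above 1. Tails of A or U are misread where the placed part stops inside the listed sequence. let-7i-5p, among the 39, was placed from 1000 to 1017, short of its listed 22 nt. In post-reproduction 11.1% of its inserts were 1 base longer and ended in A, but its A tail was 0.0351%. Such miRNAs were not left out.

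**Figure D2:**
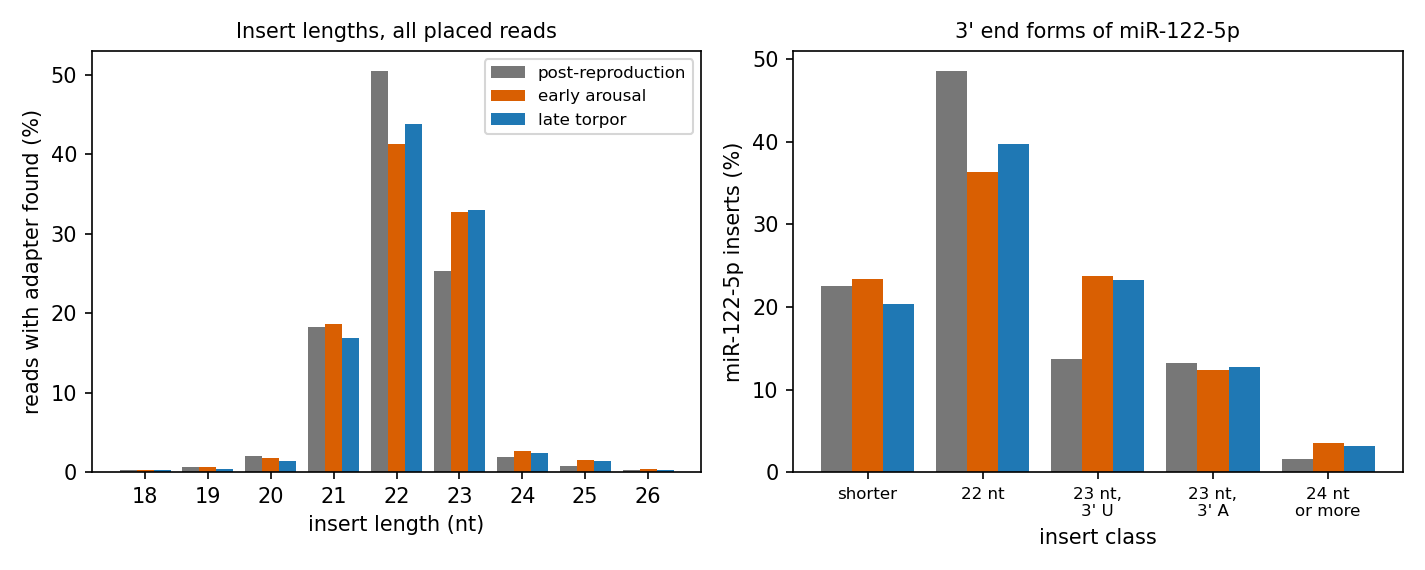
Left, share of reads with the adapter found (y axis, %) by insert length (x axis, nt) in the 3 libraries; right, share of miR-122-5p inserts (y axis, %) by 3′ end form, where 22 nt is the listed length. Bars start at 0 and each is 1 library. The 23 nt form ending in U held 13.7% of miR-122-5p inserts in post-reproduction and 23.8% and 23.3% in early arousal and late torpor, while the 23 nt form ending in A held 13.2%, 12.4% and 12.8%.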

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

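Sequences matched to no listed miRNA were outside every miRNA ratio of the report, and 7 of those reported here, each with at least 1000 reads, differed at least 4-fold between the highest and the lowest library. The tests of fragment number and of size selection given here were chosen after the results were seen, except the test over 44 other unmatched inserts. Reads that no matching rule assigned to a listed miRNA made up 5.08% of placed reads in post-reproduction, 6.25% in early arousal and 3.83% in late torpor. No RNA class is assigned to them, since no reference sequence was used here.

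The most abundant pattern was in inserts that begin with CGCGACCTCAGATCAGACG. The 20 nt form CGCGACCTCAGATCAGACGT was 10.7-fold higher in post-reproduction than in late torpor (9.97 to 11.5; 8893 against 852 reads). The 19 nt form CGCGACCTCAGATCAGACG was 11.4-fold higher in early arousal than in late torpor (10.6 to 12.3; 9446 against 800 reads). Between early arousal and post-reproduction the forms went opposite ways, with ratios of 2.56 for the 19 nt form and 0.521 for the 20 nt form. The tests that follow compare late torpor with post-reproduction only. A loss of 19 and 20 nt inserts in size selection is argued against: over 41 miRNAs the share of such inserts had a median ratio of 0.997, with an SD of 0.316 on the log2 scale and none at 0.25 or lower. The median over 44 other unmatched inserts of that length was 0.979, but with an SD of 2.97 on the log2 scale it decides nothing. Fewer fragments of the parent RNA stay open, because the other lengths disagree. Inserts of 22 to 26 nt with the same start had a late torpor to post-reproduction ratio of 1.07 (0.971 to 1.18; 882 against 804 reads), which taken alone argues against it. Inserts of 18 nt had 0.546 and those of 21 nt 0.472, and all lengths other than 19 and 20 nt together had 0.623 (0.591 to 0.657). Over all lengths from 18 to 26 nt the reads fell from 16078 to 3936, a ratio of 0.239. A different cut or trimming of this RNA between stages stays open as a hypothesis, as do causes in the making of single libraries.

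Among 30-base reads without a found adapter, CGCTAAACCATTCGTAGACGACCTGCTTCT was 5.74-fold higher in early arousal than in late torpor (5.21 to 6.33). Over the same pair of libraries, CCCCCCACTGCTAAATTTGACTGGCTTTTT was 6.27-fold higher (5.47 to 7.21) and CTGGATGATGATAAGAAGATAACTGATTTC 4.81-fold (4.09 to 5.69). Other forms of the first and the second of these differed less over the same pair. A 25 nt insert within the first, with 5117 reads, had a ratio of 1.17, and the 30-base form one base further on, GCTAAACCATTCGTAGACGACCTGCTTCTC, had 2.46. The second differs in its last bases from CCCCCCACTGCTAAATTTGACTGGCTTTCG, with 15943 reads and a ratio of 1.69, and from forms with ratios of 2.01 and 2.53. The 19 nt insert GCCCGGATAGCTCAGTCGG was 5.66-fold higher in early arousal than in post-reproduction (4.77 to 6.74; 938 against 156 reads). The 19 nt insert AAGTAAAAGGAACTCGGCA had 1037 reads in post-reproduction, 16 in early arousal and 4 in late torpor, a ratio of 266 between the first and the last of these.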

How the results depend on the processing

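The alternatives were fixed before the data were examined, except the scaling over 2 libraries and the error-free adapter. No paired analysis was possible because each stage is 1 library and no test was made. Over 1604 alternative values of named miRNA ratios, none of those past 2-fold with at least 100 reads changed direction, 1186 stayed within the counting interval of the reported value and 418 did not. The sign differed in 126 in all. Of 288 list medians, 244 stayed within their interval and 41 differed in sign, none of them outside the central 95% of random lists. Scaling to plain miRNA reads shifted log2 ratios of early arousal by 0.12 over post-reproduction and 0.17 over late torpor, and scaling to all placed reads shifted the latter by 0.12. The other scaling shifts were under 0.1 in size. The let-7 median in early arousal over post-reproduction (log2 -0.07) turned to 0.06 and 0.02 under these scalings. The numbers of miRNAs past the limit, reported as 3 for late torpor over post-reproduction, 5 for early arousal over post-reproduction and 2 for early arousal over late torpor, moved as follows in that order of comparisons. A minimum of 10 reads gave 6, 9 and 7, a minimum of 1000 reads 1, 2 and 0, and no minimum 18, 21 and 16, as more or fewer miRNAs were compared. A 1.5-fold limit gave 8, 15 and 12, and a 3-fold limit 0, 1 and 1. Median-of-ratios scaling gave 2, 4 and 2, ending the calls of miR-200a-3p (log2 -0.996 in the first) and miR-152-3p (-0.98 in the second). Plain scaling gave 3 and 4 in the second and the third comparison, and scaling to all placed reads 3 in the second, through the shift. Shifted starts gave 2, 6 and 2, and 1 internal mismatch 2, 5 and 2. The mismatch ended the calls of miR-10a-5p and miR-200a-3p in the first and added miR-144-3p there (log2 1.004). Identical reads only gave 1, 4 and 1. miR-10a-5p in the first (94 reads) and miR-144-3p in the third (15 reads) then missed the minimum, miR-200a-3p in the first (36 reads) missed the minimum and the limit, and in the second miR-152-3p (-0.96) and miR-486-5p (-0.62) missed the limit. There miR-181c-5p (19 reads) and miR-200a-3p (30 reads) missed the minimum, miR-1-3p, miR-181b-5p and miR-378a-3p passed the limit anew, and only miR-184-3p was kept. Leaving out multiply placed reads gave 3, 4 and 1, since miR-486-5p had no other reads. Seed families gave 3 in each of the first and second and 2 in the third, with members summed. Counting distinct sequences, 22 nt inserts held 25.2%, 24.1% and 24.7% in post-reproduction, early arousal and late torpor, and 23 nt inserts 20.7%, 22.5% and 23.3%. Without reads assigned by the main matching rule, 22 nt inserts held 36.5%, 36.8% and 36.0%, and 23 nt inserts 17.4%, 23.7% and 21.4%. The remaining inserts still include miRNA reads with a shifted start or an internal mismatch. With an error-free adapter, the miR-122-5p form with a 3′ U held 15.0%, 24.7% and 24.1% and the tail of A bases 17.0%, 15.3% and 15.6%, in the same order. The cause of the difference in the A tail was not tested, while tests of the 3′ U form are given below. Depth limits the low end: miR-34a-5p, chosen after its value was seen, had 1 read in post-reproduction against 6 in late torpor, a ratio of 5.85 with an interval of 0.71 to 269.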

Other observations

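Several liver miRNAs began at another base than the listed one, which moves the seed that pairs with targets. For miR-101-3p, 50% of the reads in post-reproduction (exact interval 49.5 to 50.4), 52.0% in early arousal (51.6 to 52.5) and 50.5% in late torpor (50 to 51) had a start shifted by up to 2 bases. For miR-140-3p the share was 69.9% in post-reproduction (69.2 to 70.5), 77.4% in early arousal (76.8 to 77.9) and 71.0% in late torpor (70.3 to 71.7), so early arousal lay outside the counting intervals of the others. The start of miR-122-5p was nearly fixed, with 0.0923%, 0.124% and 0.128% shifted reads in the same order. These miRNAs were singled out after their values were seen.

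Marker miRNAs of other tissues were present at uneven levels. miR-1-3p, typical of heart and skeletal muscle, had 8746, 16752 and 12456 reads in post-reproduction, early arousal and late torpor, whereas miR-133a-3p, made from the same primary transcripts, had 0, 0 and 1. That 1 read was placed, at 3 positions, so the scaffolds hold a matching locus; the cause of the gap was not tested. The neural miR-124-3p stood at 411, 291 and 309 CPM and miR-9-5p at 252, 343 and 241.

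The test with an error-free adapter was chosen after the result was seen. The longer form of miR-122-5p with a 3′ U, as a share of that form and the listed one, was 22% in post-reproduction, 39.6% in early arousal and 37.0% in late torpor. Errors that move the found end are argued against, because reads with an error-free adapter gave 25.1%, 40.9% and 38.1%, and the lower of the ratios to post-reproduction was 1.52. A shift of 3′ ends in all miRNAs could be part of the cause. Over 40 other miRNAs the median ratio of the same share was 1.2 in early arousal and 1.22 in late torpor, in between the values fixed beforehand for either outcome, and 35 and 32 of the 40 lay above 1. Without the filter for an error-free adapter, as for the 40, miR-122-5p had ratios of 1.80 and 1.68, which 4 and 6 of the 40 exceeded. Whether the rest reflects hibernation or the making of single libraries cannot be told apart with 1 library per stage.

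Reads of miR-122-5p in early arousal carried a substitution at base 19 in 1.57% of cases, against 0.388% in post-reproduction and 0.206% in late torpor. A change of miR-122-5p itself is argued against, because 24 of 25 other miRNAs also had a higher share in early arousal, with a median ratio of 4.58 (range 0.822 to 18.9). let-7f-5p, with a ratio of 2.48, was left out of that count; with it the values are 25 of 26 and 4.38. A base-calling fault in that sequencing cycle of the early arousal library is consistent with this value of 4.58.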
